A study of Mus musculus with 6 samples.

How the data were processed

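The data are 6 poly(A) RNA-seq libraries of mouse epididymal white adipose tissue, 3 from mice kept at 4 °C for 24 h and 3 from control mice. Per the labels' protocols, frozen tissue was homogenised, total RNA was isolated on spin columns, and strand-specific paired-end libraries with reads of 50 nt were made. Per the submitters' processing notes, bcl2fastq, cutadapt and Salmon were used with the mouse build GRCm38; their versions and settings are not given in the sources used here. The authors deposited 1 Salmon table per library with 140658 transcripts, holding for each the estimated counts, which need not be whole numbers, the TPM (abundance scaled for transcript length and depth) and an effective length. The deposited estimated counts come from Salmon's sharing of reads among overlapping transcripts, per the file headers. The deposited TPM values were not tested, because they keep no depth.

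Transcript identifiers were joined to GENCODE M21, which is built on GRCm38. With version numbers 139921 identifiers matched, all with the same transcript length as in the files, and 140137 matched without them. The remaining 521 identifiers, with 0.124 to 0.394% of the counts of a library, name no gene and were left out of library sizes and tests. Coordinates are those of M21, counted from 1. Estimated counts were summed over the transcripts of each gene, giving 54356 genes, and rounded to whole numbers.

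Genes were tested in R 4.3.3 with edgeR 4.0.16. Genes passed filterByExpr with its default minimum count of 10, needed in at least 3 libraries, and minimum total of 15, libraries were scaled by TMM, and glmQLFit with robust estimation and glmQLFTest compared cold with ctrl (two-sided, no covariate). P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Standard errors of log2 fold changes were taken from the quasi-likelihood F statistic. CPM values use TMM-scaled library sizes and are given as mean ± SD of 3 libraries. An exact permutation test of 3 libraries against 3 cannot go below p = 0.10, so single values rest on the model across genes. Transcripts were tested the same way on rounded transcript counts. Transcript usage was tested with diffSpliceDGE on the transcript fit, over genes with at least 2 transcripts kept. Resampled estimates were not used here, so the uncertainty of sharing reads between transcripts is not modelled on its own in the p-values.

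Groups, tests, gene lists, the rule for named genes and most alternatives were set before the data were examined. There were 32 lists, 18 of pathways and 14 of cell type markers, with 465 genes in all, and each is named with its result. The 31 lists with at least 5 tested genes were tested with camera (limma 3.58.1) at its preset correlation of 0.01, adjusted over lists. None of the 5 lists called this way held with an estimated correlation (1 list at an unadjusted p under 0.05), and none passed by fry's directional test (6 at an unadjusted p under 0.05). Genes were named by rule: the 10 with the largest rise and the 10 with the largest fall among called genes with a mean of at least 5 CPM, no overlap between groups and a symbol that is not a predicted or clone name; up to 4 members with the smallest p per list; 12 genes chosen in advance for cold and fat biology (Ucp1, Cidea, Dio2, Ppargc1a, Elovl3, Prdm16, Pck1, Lep, Adipoq, Fasn, Pnpla2 and Cirbp); and the 8 genes with the smallest usage p at a mean of at least 5 CPM with a similar symbol. Scd1, Socs6, Crisp1, Spata18, Gm4737 and Tcp11, and the genes given in the observations, were named after their values were seen. Some genes that fall under this rule are not reported here. The order of libraries given beside some genes, and the lists of motile cilium, epithelial junction, absorptive duct and seminal vesicle genes, were chosen after the data were examined.

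Libraries of one group were compared before averaging. All pairs differed beyond sampling noise (chi-square per degree of freedom of 12.0 or more), so none looks like the same library counted again, and all 6 were kept. That they come from separate mice rests on the mouse numbers, not on this value. The mouse numbers differ between groups, and no label gives a sequencing batch or date. The alternatives were RLE size factors, no low-count filter, an offset for mean transcript length, DESeq2 1.42.0, other set tests, limma's diffSplice, the gene-level F test, a minimum share of 10 percent per transcript, and leaving out each library in turn. A covariate and further subsets were added after the data were examined.

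The steps were tested on simulated data drawn from the means and library sizes of cold against ctrl. Over 17852 genes, 30% of 50 genes changed 1.5-fold were recovered, 52% at 2-fold, 90% at 4-fold and 82% at 0.25-fold, with 5.22% of calls false. For 31 lists with no change, 1 list was called. For transcript usage with 200 changed genes, edgeR recovered 26 with 44 false calls when every transcript had its own dispersion, and 35 with 0 false calls when dispersions followed one trend; limma recovered 81 with 35 false and 76 with 3 false. Intervals and floors for a count of 0 (3 counts) cover counting error only.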

Results

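Polyadenylated RNA of epididymal white adipose tissue (eWAT), the visceral fat pad that lies along the epididymis, was sequenced from 6 male C57BL/6N mice aged 20 weeks. Of these, 3 mice (cold 7, cold 12 and cold 16) are labelled cold and 3 (ctrl 5, ctrl 6 and ctrl 10) are labelled as controls. The treatment text, the same for all 6, describes single housing at 4 °C for 24 h before the tissue was taken, and the general housing temperature is given as 22 to 24 °C. Whether the controls were housed singly is not given in the sources used here. The numbers are mouse identifiers, so the libraries come from separate animals and the p-values below measure the spread between these mice. Total estimated counts were 24176464, 22969181 and 19735167 in ctrl 5, ctrl 6 and ctrl 10. They were 22903050, 25142603 and 28608052 in cold 7, cold 12 and cold 16. The stearoyl-CoA desaturase gene Scd1 was the most abundant gene in all 6 libraries, with 2.25 to 3.31% of counts, and mitochondrially encoded genes took 3.85 to 5.71%. The first principal component of log2 CPM (counts scaled to library size) held 62.8% of the variance and separated the groups. On it, ctrl 5 was the control nearest to the cold group and cold 7 the cold library nearest to the controls. All 6 libraries stood on it in the order of their mean log2 CPM of motile cilium genes, a list chosen after the data were examined. The component therefore cannot be read as an effect of cold alone.

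The first comparison asks which genes differed between cold-exposed and control eWAT. Of 17852 genes tested, 415 rose and 101 fell in the cold. The genes that rose were mostly of low abundance, with a median fold of 5.52 and a median level of 2.65 CPM over all libraries, and 285 of them lay below 5 CPM. The genes that fell were more abundant, with a median of 49.2 CPM, and changed less, with a median log2 fold change of -0.51. All 516 had every cold library on one side of every control library, which held for 23.8% of all genes tested and would hold for 10% by chance.

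Among genes past the threshold with a mean of at least 5 CPM and a symbol that is not a predicted or clone name, Prom2 had the largest rise. Prom2, a membrane glycoprotein of epithelial cell protrusions (chromosome 2, 127526473 to 127541467, GRCm38), went from 1.57 ± 1.92 CPM in controls to 50.4 ± 10.1 CPM in the cold (SD, n = 3 each), a log2 fold change of 4.93 (SE 0.74, adjusted p = 0.0417). The gluconeogenic phosphatase gene Fbp1 (chromosome 13, 62864753 to 62888282) went from 0.377 ± 0.473 to 11.1 ± 3.82 CPM, a log2 fold change of 4.79. The mucosal chemokine Ccl28 (chromosome 13, 119623819 to 119654359) went from 1.03 ± 0.725 to 21.1 ± 11.1 CPM, a log2 fold change of 4.32. E-cadherin, Cdh1 (chromosome 8, 106603351 to 106670246), went from 0.740 ± 0.790 to 14.7 ± 4.97 CPM, a log2 fold change of 4.25 (SD, n = 3 each). The epithelial serine protease Tmprss2 rose by 4.22, the prostaglandin D synthase Ptgds by 3.84 and the meiotic cohesin subunit Rec8 by 3.81 on the log2 scale. The transcriptional coactivator Cited4 and Gramd2 each rose by 3.27 and the adaptor protein Grb7 by 3.18. Adjusted p-values of these 10 genes lay between 0.0313 and 0.0496 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With no low-count filter all 10 missed the threshold (adjusted p between 0.0825 and 0.166), and with the transcript length offset Cdh1, Tmprss2 and Rec8 did (adjusted p = 0.0629, 0.203 and 0.0507), as did Prom2 without cold 7 (0.0554). In 9 of the 10, all but Ptgds, ctrl 5 was the highest control and cold 7 the lowest cold library. That order held in 249 of the 415 genes that rose and in 13.7% of genes not called. For the epithelial genes among them, a rise inside the fat cannot be told apart from tissue of the male reproductive tract carried over with it.

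Among the genes that fell, Cdh23, a cadherin known from inner ear hair cells (chromosome 10, 60302748 to 60696490), went from 13.8 ± 1.35 to 4.11 ± 0.813 CPM (SD, n = 3 each), a log2 fold change of -1.75 (SE 0.18, adjusted p = 0.021). The neuronal calcium sensor Hpca (chromosome 4, 129111570 to 129122036) changed by -1.50, the secreted phospholipase Pla2g2d (chromosome 4, 138775735 to 138782046) by -1.08, Rprml (chromosome 11, 103649570 to 103650579) by -1.04 and the collagen VI chain Col6a6 (chromosome 9, 105687809 to 105828160) by -1.01 on the log2 scale. Col6a6 went from 41.5 ± 2.69 to 20.7 ± 1.75 CPM (SD, n = 3 each). Smaller falls were seen for the MYC family gene Mycl (-0.87, adjusted p = 0.021), Prrt1 (-0.83), the inositol transporter Slc2a13 (-0.83) and the organic anion transporter Slco2b1 (-0.77). Slco2b1 (chromosome 7, 99657804 to 99711340) went from 204.6 ± 17.2 to 119.6 ± 10.4 CPM (SD, n = 3 each). Adjusted p-values of these 9 genes ran from 0.021 to 0.041, and Slc2a13 missed the threshold with the transcript length offset (adjusted p = 0.0507). Hpca, Prrt1 and Slc2a13 missed it without ctrl 5 (adjusted p = 0.0654, 0.0697 and 0.0814), and Hpca without cold 7 (0.0616). Of these 9 genes only Mycl had ctrl 5 as highest control and cold 7 as lowest cold library. A gene lowered by carried-over tissue would have the reverse order, which was not counted. For genes that fell, this order therefore does not tell whether they follow such tissue.

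The number of calls changed with the libraries included. The direction of the 516 genes did not change with any 1 library left out, which their lack of overlap between groups makes near certain in advance. All 516 then had an unadjusted p under 0.05, with a median absolute log2 fold change of 1.90 to 2.27 (2.04 with all 6 libraries) and a median SE of 0.306 to 0.403 (0.354). They were selected by p in these same libraries, so neither value is independent support. No gene, those named here included, passed without ctrl 6, ctrl 10 or cold 12 by edgeR, with 3071, 2835 and 2546 genes at an unadjusted p under 0.05 1180, 1107 and 747 calls by DESeq2, and a smallest adjusted p of 0.0589, 0.0947 and 0.0562, and 3 passed without cold 16 (Spata18, Gm4737 and Tcp11, named after their values were seen), whereas 696 passed without ctrl 5 and 1090 without cold 7. Among alternatives chosen after the data were seen, 1230 genes passed with ctrl 5 and cold 7 both left out, among them 433 of the 516. With the mean level of motile cilium genes as a covariate, also chosen then, 0 passed by edgeR (815 at an unadjusted p under 0.05, smallest adjusted p 0.190). Under it 504 of the 516 kept their direction at a median absolute log2 fold change of 0.65 (median SE 0.63). Of the covariate's variance 82.5% lay between the groups, so a loss of calls under it cannot separate cold from carried-over tissue. The same limit holds for the lists tested with it below.

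**Figure D1:**
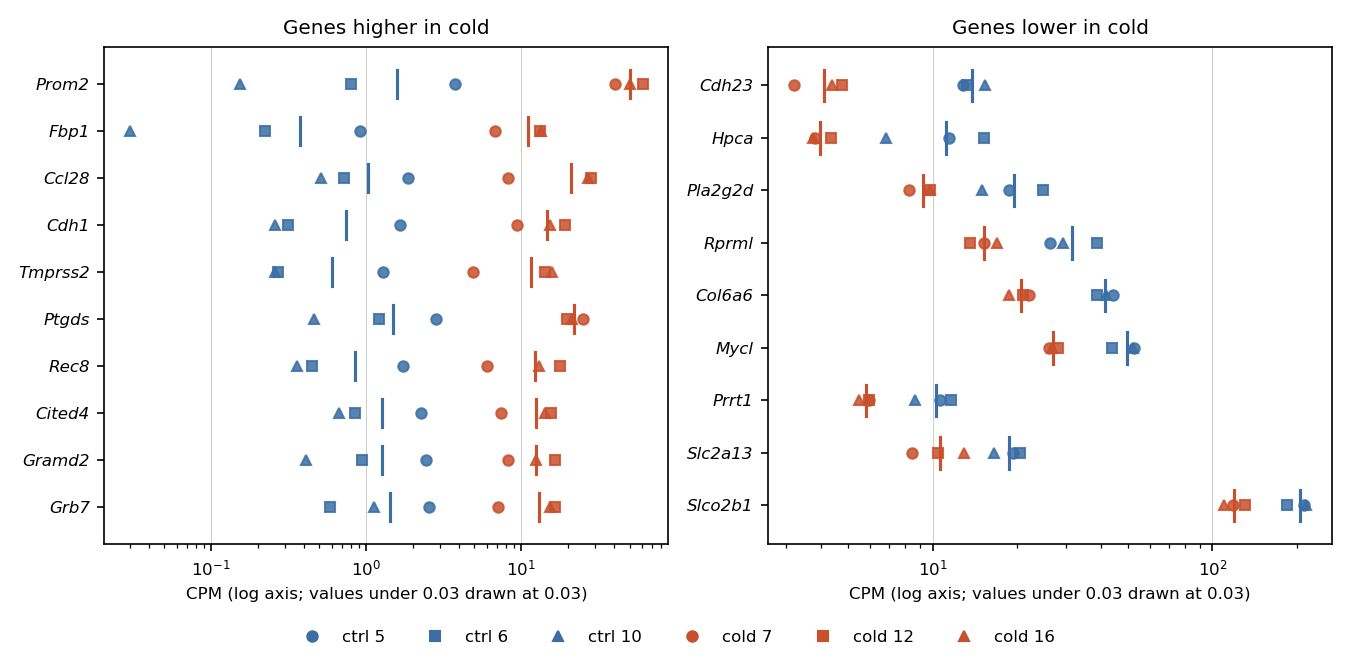
Level of the 10 genes with the largest rise (left) and 9 of the 10 with the largest fall (right) in each library, as CPM on a log axis. Each symbol is 1 mouse, and vertical strokes are group means; for Prom2 the 3 cold libraries sit between 40.5 and 60.8 CPM and the 3 controls between 0.154 and 3.76 CPM.

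Genes of heat production in brown and beige fat were compared next. Dio2, the deiodinase that activates thyroid hormone, rose from 0.366 ± 0.041 to 2.29 ± 0.807 CPM (SD, n = 3 each), a log2 fold change of 2.64 (SE 0.38, adjusted p = 0.025 by edgeR). It was the only one of 20 tested members of the thermogenic list to pass over all genes, and 6 members, all higher, passed when p-values were adjusted over the list alone. The list as a whole was higher in the cold by camera (median log2 fold change 0.35, mean 0.77, adjusted p = 0.0032). Its members ran from -0.34 to 4.08, so Dio2 was not the largest rise, and the mean lay well above the median. The list had adjusted p = 0.593 with an estimated correlation between genes and 0.825 with the motile cilium covariate. By camera at its preset correlation, every other split of the libraries gave more lists (6 to 14) than the real one (5), so these list calls are weak. The transcriptional coactivator Ppargc1a stood at 0.74 (SE 0.18, adjusted p = 0.074), Clstn3 at 0.66 (adjusted p = 0.052) and the glycerol kinase gene Gk at 1.72 (adjusted p = 0.056). Cidea stood at 0.16 and Prdm16 at 0.01, the latter at -0.03 with the transcript length offset. Uncoupling protein Ucp1 had 10, 0 and 0 counts in controls and 3, 7 and 1 in the cold, and the fatty acid elongase Elovl3 had 0, 2 and 0 against 4, 2 and 1, so a change in either was not detectable at this depth. In 7 of the 20 tested members, Gk and Cidea among them, ctrl 5 was the highest control and cold 7 the lowest cold library, against 13.7% of genes not called.

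Genes of fat storage and endocrine function moved in both directions. The hormone gene Lep rose from 1220 ± 111 to 1867 ± 265 CPM (log2 fold change 0.61, SE 0.13, adjusted p = 0.044) and the lipogenic regulator Thrsp from 652 ± 49.8 to 1090 ± 177 CPM (0.74, SE 0.13, adjusted p = 0.032; SD, n = 3 each). The adipsin gene Cfd fell from 9300 ± 796 to 6197 ± 614 CPM (-0.59, SE 0.12, adjusted p = 0.044; SD, n = 3 each). Adiponectin, Adipoq, was at -0.09, the gluconeogenic enzyme Pck1 at -0.44, the insulin receptor substrate Irs2 at -1.03 and fatty acid synthase, Fasn, at -0.44 on the log2 scale, none past the threshold. Of 18 adipokine and insulin signalling genes, 1 rose and 1 fell (1 up and 2 down adjusted over the list alone; median -0.05, camera adjusted p = 0.499). Of 19 lipogenic genes, Thrsp rose and no other passed over all genes (2 up adjusted over the list alone, the other being the desaturase Fads2 at 1.15; median 0.01, adjusted p = 0.499). Of 13 adipocyte markers 2 rose, Lep and Thrsp (3 up and 1 down adjusted over the list alone; median -0.04, mean 0.01, camera direction up, adjusted p = 0.891). Without ctrl 5, Lep and Cfd missed the threshold (adjusted p = 0.0842 and 0.0943). In Thrsp and Fads2, which were higher, and in Fasn, which was lower, ctrl 5 was the highest control and cold 7 the lowest cold library. That order held in 9 of the 19 lipogenic genes, against 13.7% of genes not called.

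No gene of the lipolysis list passed over all 17852 genes. The triglyceride lipase gene Pnpla2 was at 0.46 (adjusted p = 0.062) and the adenosine receptor Adora1 at 0.51, against -0.70 for the beta-adrenergic receptor Adrb3. In this list 4 members passed upward and 1 downward adjusted over the list alone (18 genes, median -0.10, camera adjusted p = 0.891). In fatty acid oxidation, the mitochondrial carrier Ucp3 rose by 0.48 and the peroxisomal enzyme Ehhadh fell by 0.48 on the log2 scale (adjusted p = 0.041 and 0.050), as over the list alone (23 genes, median 0.05, camera adjusted p = 0.731). Both missed the threshold with the transcript length offset (adjusted p = 0.0698 and 0.0534) and without ctrl 5 (0.0617 and 0.0702). In triglyceride synthesis and glyceroneogenesis none of 12 passed (1 up adjusted over the list alone, median 0.06, adjusted p = 0.764). None of 10 futile cycling genes passed (2 up adjusted over the list alone, median 0.12, adjusted p = 0.382), with creatine kinase Ckb at 0.95, in which ctrl 5 was the highest control and cold 7 the lowest cold library, and the calcium pump Atp2a2 at 0.34. The 30 nuclear-encoded respiratory chain genes (median 0.03, adjusted p = 0.382) and the 13 mitochondrially encoded genes (median 0.18, adjusted p = 0.099) held no call, over all genes or adjusted over the list alone, although all 13 of the latter had positive values.

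**Figure D2:**
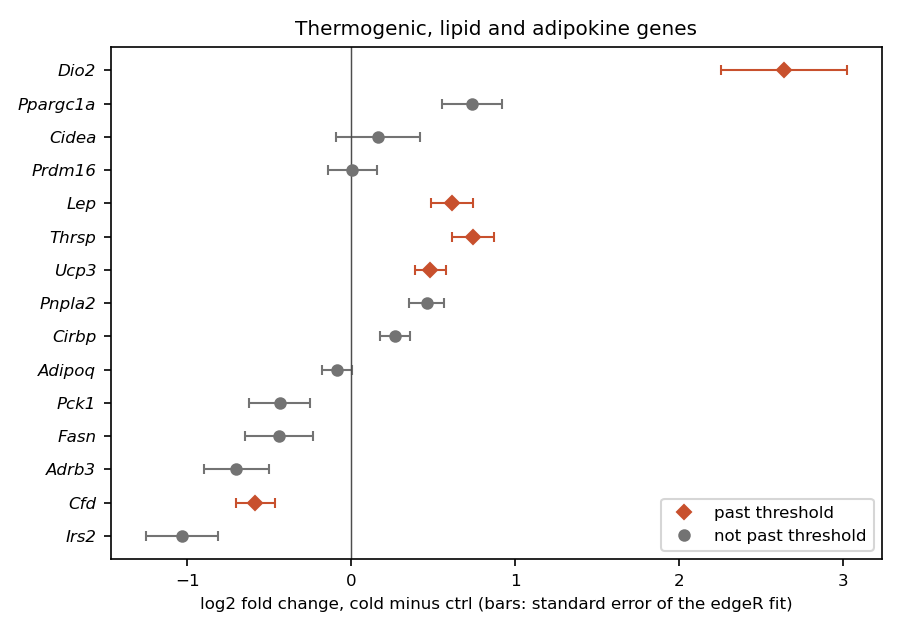
Log2 fold change, cold minus ctrl, of 15 thermogenic, lipid and adipokine genes, with bars for the standard error of the edgeR fit (n = 3 mice per group). Diamonds mark the 5 genes past the threshold: Dio2, Lep, Thrsp and Ucp3 are higher and Cfd is lower.

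Hormone and antiviral response lists held 1 call each among single genes. The cell cycle inhibitor Cdkn1a rose from 15.4 ± 3.86 to 32.0 ± 4.24 CPM (SD, n = 3 each), a log2 fold change of 1.06 (adjusted p = 0.037), and was the only called gene of 16 glucocorticoid receptor targets (3 up adjusted over the list alone). The lipocalin Lcn2 was at 3.13 and Klf9 at 0.33. This list was higher by camera (median 0.12, adjusted p = 0.030), with adjusted p = 0.593 with an estimated correlation, and missed the threshold without ctrl 10 (adjusted p = 0.0614), without cold 7 (adjusted p = 0.0636) and with the motile cilium covariate (adjusted p = 0.877). The antiviral gene Bst2 fell by 0.42 on the log2 scale (adjusted p = 0.041), over all genes and adjusted over the list alone, as 1 of 18 interferon-stimulated genes. That list was lower by camera (median -0.19, adjusted p = 0.0114), with adjusted p = 0.960 with an estimated correlation, and missed the threshold without ctrl 5 (adjusted p = 0.0838), without cold 16 (adjusted p = 0.123) and without ctrl 5 and cold 7 together (adjusted p = 0.104). Bst2 itself missed it with the transcript length offset (adjusted p = 0.0799), without ctrl 5 (0.0979) and without cold 7 (0.0506). The myelin gene Ncmap rose, from 0.192 ± 0.084 to 1.99 ± 0.936 CPM (SD, n = 3 each), as the one called gene of 8 Schwann cell markers (also 1 adjusted over the list alone; median 0.03, adjusted p = 0.657). In Lcn2 and Ncmap, which were higher, ctrl 5 was the highest control and cold 7 the lowest cold library. Bst2 had that order too, but it fell, and for genes that fell the order does not mark carried-over tissue.

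Several other pathway lists held no call over all genes. One was the group of beta-adrenergic and cAMP response genes (18 genes, 1 up and 1 down adjusted over the list alone, median -0.18, camera adjusted p = 0.117). Others were the circadian clock (17 genes, 2 up and 3 down adjusted over the list alone, median -0.11, mean 0.07, adjusted p = 0.551, with Npas2 at 1.85, camera direction down) and cold-inducible RNA-binding and heat shock genes (14 genes, 1 up adjusted over the list alone, median 0.17, adjusted p = 0.099, with Hspa8 at 0.34 and the cold-inducible Cirbp at 0.26). Cholesterol synthesis had 1 gene down adjusted over the list alone, Insig1 at -0.44 being the lowest p (20 genes, median 0.03, mean 0.003, camera direction down, adjusted p = 0.891). Extracellular matrix (18 genes, median -0.002, mean 0.03, camera direction down, adjusted p = 0.833), cell cycle (18 genes, median -0.21, adjusted p = 0.170) and unfolded protein response genes (16 genes, median 0.11, adjusted p = 0.499) had none in either adjustment.

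**Figure D3:**
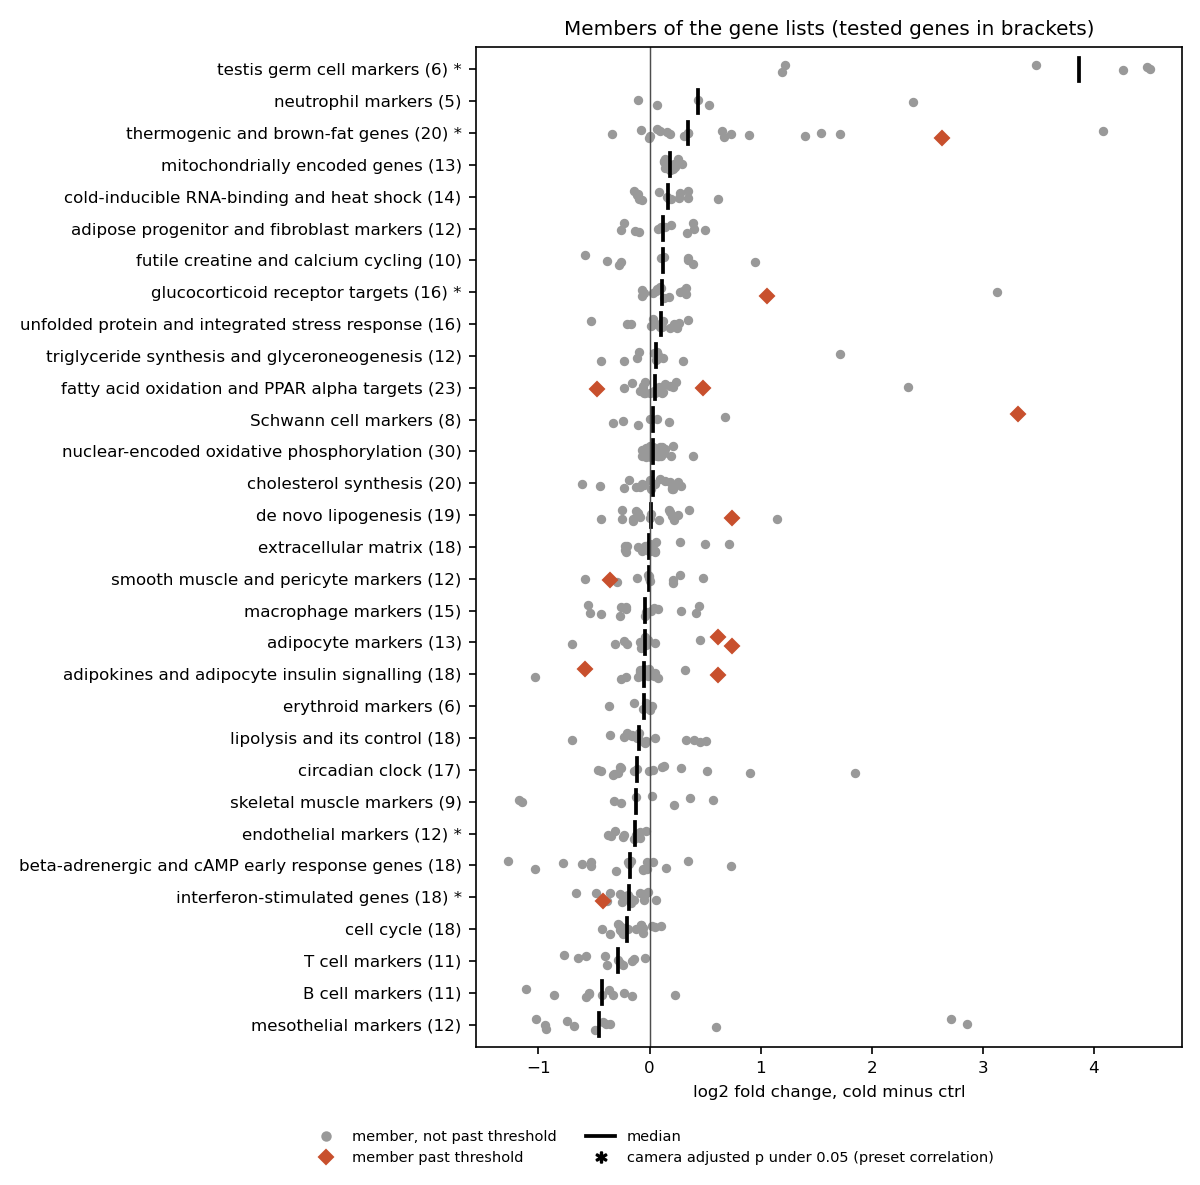
Log2 fold change, cold minus ctrl, of every tested member of 31 gene lists, with the list median as a black stroke and members past the threshold as diamonds. Stars mark the 5 lists past the camera threshold with the preset correlation; testis germ cell markers have the highest median at 3.87 and mesothelial markers the lowest at -0.45.

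Markers of blood vessels, immune cells and other resident cells were also compared. Every one of 12 endothelial markers was lower in the cold, none past the threshold singly or adjusted over the list alone, with Tie1 at -0.37 and Egfl7 at -0.35. The list was lower by camera (median -0.13, adjusted p = 0.0215), with adjusted p = 0.593 with an estimated correlation. It missed the threshold with ctrl 5 and cold 7 both left out (adjusted p = 0.131) and with the motile cilium covariate (adjusted p = 0.349). The pericyte gene Notch3 fell by 0.36 on the log2 scale (adjusted p = 0.045), 1 of 12 smooth muscle and pericyte markers (2 down adjusted over the list alone, with Rgs5 at -0.58; median -0.005, adjusted p = 0.551). Notch3 missed the threshold with the transcript length offset (adjusted p = 0.114) and without ctrl 5 (0.125). Macrophage (15 genes, median -0.04, adjusted p = 0.551), T cell (11 genes, median -0.29, adjusted p = 0.113) and B cell markers (11 genes, median -0.42, adjusted p = 0.099) held no call in either adjustment. The same holds for progenitor and fibroblast (12 genes, median 0.12, adjusted p = 0.891), skeletal muscle (9 genes, median -0.12, adjusted p = 0.551) and erythroid markers (6 genes, median -0.05, adjusted p = 0.774). Neutrophil markers had 1 gene up adjusted over the list alone, S100a9 at 2.37 (5 genes, median 0.43, adjusted p = 0.382). Mesothelial markers had 2 up adjusted over the list alone, the keratins Krt18 and Krt8 at 2.86 and 2.71, while the list median was -0.45 and its mean 0.02 (12 genes, camera direction down, adjusted p = 0.891). In both keratins ctrl 5 was the highest control and cold 7 the lowest cold library.

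Markers of male reproductive tissue differed between single libraries. All 6 tested testis germ cell markers were higher in the cold, led by the sperm chromatin genes Prm2 at 4.51 and Tnp2 at 4.48, with none past the threshold over all genes and 2 up adjusted over the list alone. The list was higher by camera (median 3.87, adjusted p = 0.0114), with adjusted p = 0.960 with an estimated correlation, and missed the threshold without cold 7 (adjusted p = 0.128) and without ctrl 5 and cold 7 together (adjusted p = 0.468). The 10 markers summed to 81.7 CPM in cold 7 and 61.7 CPM in cold 12, against 6.39 CPM in cold 16 and 2.73 to 8.09 CPM in controls. Of 14 epididymis epithelium markers only Adam7 passed the count filter, which asks for counts in at least 3 libraries (log2 fold change 5.92, adjusted p = 0.333, no call adjusted over the list alone). The sperm-coating protein gene Crisp1, left out because its counts lay in 1 library, had 2555 counts in cold 7 and at most 5 in any other library. These epididymis markers summed to 143.2 CPM in cold 7 and to between 0.565 and 2.06 CPM in the other 5 libraries.

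**Figure D4:**
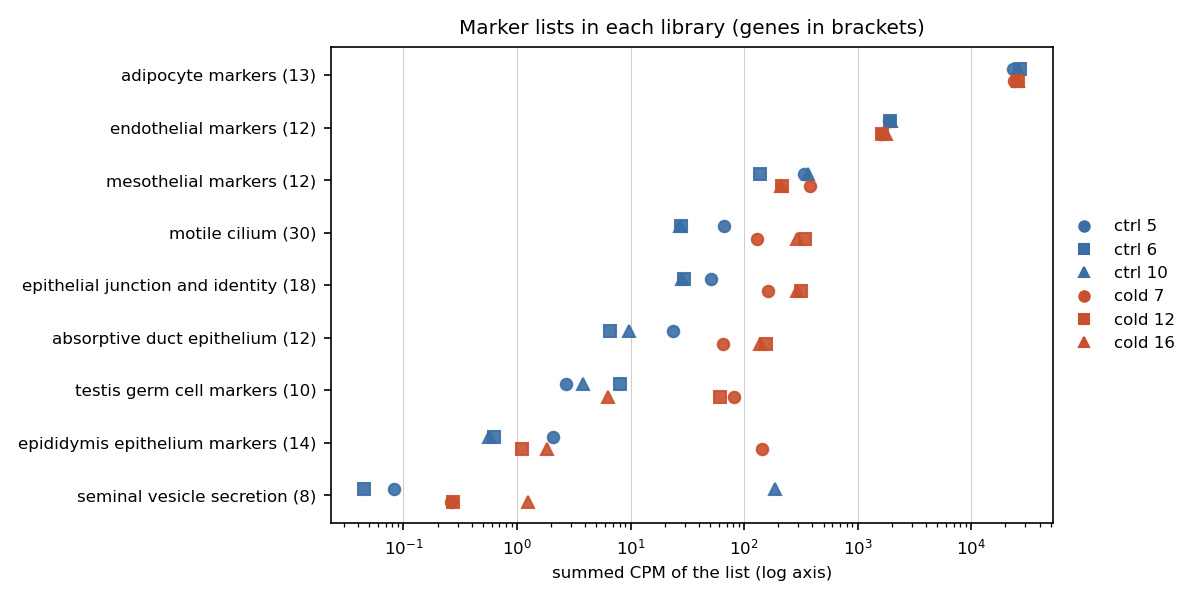
Summed CPM of 9 marker lists in each library, on a log axis, with 1 symbol per mouse. The motile cilium genes sum to 343.3, 290.8 and 129.9 CPM in cold 12, cold 16 and cold 7 against 27.2 to 66.4 CPM in controls, whereas adipocyte markers lie between 23430 and 26720 CPM in every library.

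The second comparison asks which single transcripts changed, since the files give an estimate per transcript. Of 42984 transcripts tested, 0 passed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 3503 (8.15%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.193. DESeq2 called 1182 transcripts, 902 higher and 280 lower. The fitted coefficient of variation between libraries, beyond counting noise, was 0.487 per transcript against 0.165 per gene. For transcripts it does not separate spread between mice from error in sharing reads. In simulated data of this design 2% of transcripts changed 2-fold and 26% of those changed 4-fold were recovered.

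The third comparison asks whether the shares of a gene's transcripts shifted while its total could stay the same. Of 9654 genes with at least 2 transcripts tested, 95 were called for transcript usage by edgeR's diffSpliceDGE (Simes, Benjamini-Hochberg). Other splits of the libraries, each mixing cold and control, gave 48 to 83 calls, so these calls are weak. In simulated data this test made 44 false calls beside 26 recovered genes when every transcript had its own dispersion. With one dispersion trend it made 0 beside 35. The smallest p was that of Pear1, a platelet and endothelial receptor (chromosome 3, 87747890 to 87824306). Its transcript Pear1-202 took 14.6 ± 4.15% of the gene's estimated counts in the cold and 0 of 5271 in controls, an upper limit of 0.0569% from counting error alone. Pear1-216 went from 52.5 ± 2.26 to 39.4 ± 1.46% (SD, n = 3 each, adjusted p = 1.6e-15 by diffSpliceDGE). This limit and those below leave out error in Salmon's sharing of reads between overlapping transcripts, so the true shares could be higher. The nuclear import receptor Tnpo3 (chromosome 6, 29540827 to 29609887) lost Tnpo3-202, at 15.6 ± 3.72% in controls and 0 counts in the cold (upper limit 0.0387%), and Tnpo3-201 went from 57.0 ± 4.69 to 73.4 ± 9.11% (SD, n = 3 each; adjusted p = 1.4e-08). The RNA-binding protein gene Pcbp3 (chromosome 10) gained 27.6 points in Pcbp3-206 (upper limit in controls 0.339%). The actin-binding gene Nexn (chromosome 3) gained 17.3 points in Nexn-203 (upper limit 0.418%) and the transporter gene Pqlc1 (chromosome 18) gained 14.7 points in Pqlc1-201 (upper limit 0.244%), all 3 transcripts at 0 counts in controls. The histone methylation cofactor Ash2l lost Ash2l-205 (6.37% in controls, upper limit in the cold 0.110%) and the integrator subunit Ints11 lost Ints11-202 (6.48% in controls, upper limit 0.134%), both at 0 counts in all cold libraries. The mitophagy receptor gene Bnip3l lost the minor Bnip3l-207, at 0.896 ± 0.343% in controls (SD, n = 3; 33, 25 and 39 counts) and 0 counts in the cold (upper limit 0.0235%), while Bnip3l-201 was at 79.5 and 81.2% (unadjusted p = 0.874). In all 8 genes the transcript at 0 in one group had the smallest p, and the other transcripts of these genes, Pear1-216 and Tnpo3-201 included, had unadjusted p-values of 0.0854 or more. None of these 8 genes passed the gene-level test (adjusted p between 0.597 and 0.942), and 7 of the 95 were among the 516 genes above.

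A transcript at 0 in all 3 libraries of one group and above 0 in all 3 of the other was found in 84 of the 95 called genes (88.4%). It was found in 69 of the genes not called (0.722%). Such a change is large relative to the transcript itself, but its share of the gene can be small, as for Bnip3l-207 at 0.896% in controls. The limma test diffSplice called 1 gene, the signalling suppressor Socs6 (adjusted p = 0.028), which edgeR did not call, and 22 genes passed when only transcripts with at least 10 percent of their gene's counts were kept. Leaving out ctrl 5, ctrl 6, cold 7 or cold 16 gave 151, 150, 180 and 148 genes.

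**Figure D5:**
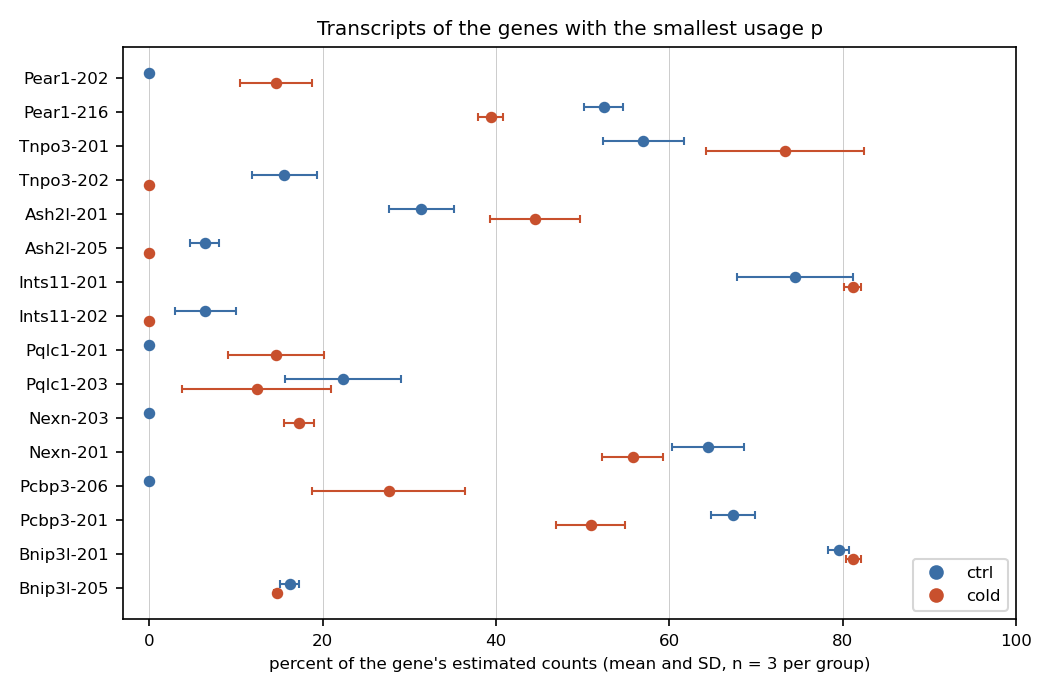
Share of the gene's estimated counts taken by the transcript that gained and the one that lost most in the 8 named genes, in percent, as mean and SD over 3 mice per group. In 7 of the 8 genes one plotted transcript lies at 0 in a whole group; for Bnip3l that transcript, Bnip3l-207, is not plotted because others moved by more points.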

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

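The fits with a covariate, without ctrl 5 and cold 7 together, and over subsets of genes were chosen after the results were seen, as were the tests of other splits for transcripts and usage. No paired analysis was possible because the groups share no mouse numbers. Gene calls numbered 526 with RLE and 411 with the length offset (513 and 348 of the 516 kept), but 924 with no low-count filter (451 kept), 1430 by DESeq2 (514 kept), 1230 without ctrl 5 and cold 7 (433 kept), and 0 by edgeR with the cilium covariate (815 at an unadjusted p under 0.05). That covariate has 82.5% of its variance between the groups. By construction fewer genes were counted at 50 CPM or more (64, with 14 higher and 50 lower) and outside the cilium order (253, with 166 higher and 87 lower). Leaving out 1 library gave 0 to 1090 genes, 4 to 9 lists, 0 transcripts and 139 to 180 usage genes. All 29 called genes among 58 named genes missed the threshold without ctrl 6, ctrl 10, cold 12 or cold 16 and under the covariate. Of the 29, 10 missed it with no low-count filter (all of at least 5 CPM with a rise over 3 on the log2 scale), 8 with the length offset, 9 without ctrl 5, 3 without cold 7 and 7 without both. The 5 lists became 9 with no filter, 0 with an estimated correlation (1 at an unadjusted p under 0.05), 0 by fry (6), 12 under the covariate and 3 without ctrl 5 and cold 7. Of the 5, the thermogenic, glucocorticoid and endothelial lists missed the threshold under the covariate (adjusted p = 0.825, 0.877 and 0.349), and the interferon, endothelial and germ cell lists did without ctrl 5 and cold 7 (adjusted p = 0.104, 0.131 and 0.468). Transcript calls were 8 with no filter and 1182 by DESeq2, and usage calls 112 by the F test, 1 by limma and 22 at a share of 10 percent. Prdm16 was at -0.027 with the length offset and between -0.054 and 0.15 with 1 library left out, and Cidea between -0.015 and 0.39. Under the covariate Cidea was at -0.71, Fads2 at -0.064, and 4 lists turned: signed -log10 adjusted p was 1.32 for lipolysis, -2.83 for de novo lipogenesis, 5.28 for extracellular matrix and 1.90 for erythroid markers. Except where fewer genes were counted, the cause was not tested. Of 10 splits of the 6 libraries, the real one included, 1 gave at least as many gene calls as the real one, which was the real one itself (516, highest other 16), and likewise 1 for usage calls (95, highest other 83). All 10 gave at least as many transcripts (0, highest other 0) and lists (5, highest other 14). With 10 splits the share is never under 0.1.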

Other observations

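The tests of carried-over tissue (except that on called thermogenic members), of mesothelium, of a cold response, of dilution and of transcripts at 0 were chosen only after the results were seen, and the genes in the next paragraphs were named after their values were seen. Among abundant genes, the growth arrest factor Gas6 fell from 435.2 ± 43.7 to 258.2 ± 44.2 CPM and the matrix proteoglycan Podn from 276.1 ± 24.9 to 166.4 ± 12.5 CPM (SD, n = 3 each), log2 fold changes of -0.75 and -0.73 (adjusted p = 0.0330 and 0.0226 by edgeR). Among genes with a mean under 50 CPM, the amino acid transporter Slc7a5 and the branched-chain aminotransferase Bcat1 rose by 1.25 and 1.97 on the log2 scale (adjusted p = 0.0421 and 0.0340). None of these 4 genes had ctrl 5 as highest control and cold 7 as lowest cold library. For Gas6 and Podn, which fell, the reverse order would be the relevant one and was not counted.

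Several markers of other tissues stood in single libraries or groups. Seminal vesicle secretion genes, 0 of 8 tested because their counts lay almost all in ctrl 10, summed to 186.3 CPM in ctrl 10 and to at most 1.26 CPM elsewhere, with Svs5 at 64.4, Svs2 at 41.2 and Svs4 at 35.7 CPM. Of 30 motile cilium genes, 11 rose and all 30 had positive values (28 up adjusted over the list alone, median 3.47). Of 17 tested epithelial junction genes 13 rose (17 adjusted over the list alone, median 2.78), and of 12 absorptive duct genes 7 rose (12 adjusted over the list alone, median 3.32). These 4 lists were written after the data were seen, and hold called genes such as Cdh1 and Prom2, so their counts are not independent evidence. The cilium regulator Foxj1 stood at 10.2, 0.983 and 0.0513 CPM in ctrl 5, ctrl 6 and ctrl 10, and at 22.2, 85.4 and 73.8 CPM in cold 7, cold 12 and cold 16 (log2 fold change 3.95, adjusted p = 0.183).

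For the epithelial, cilium and duct genes, more mesothelium, the native lining of the fat pad, is argued against by the mesothelial median of -0.45, although Krt8 and Krt18 were higher. A candidate source is ciliated duct tissue of the male reproductive tract, taken in varying amounts with the fat: 60% of the genes called higher (249 of 415) had ctrl 5 as highest control and cold 7 as lowest cold library, against 13.7% of genes not called, and 59.2% without the cilium genes themselves. The duct and epithelial genes Lrp2 and Epcam reached 67.9 and 44.5 CPM in cold 12, epididymis markers summed to only 1.10 and 1.85 CPM in cold 12 and cold 16, which argues against epididymis epithelium as the source there, and 8 of 30 cilium, 2 of 18 epithelial and 2 of 12 duct genes reached 1 CPM in every control. A response to cold inside the fat cannot be told apart from it, since 29 of 30 cilium genes had all cold libraries above all controls, and a response of varying strength would give the same order. For the thermogenic list, 35% of members (7 of 20, exact binomial 95% interval 15.4 to 59.2%) had that order, against 13.7% of genes not called (exact binomial p = 0.0136). Interval and p take genes as independent, and the share met the bound set after the results were seen. Among its called members 0 of 1 had that order. The order was also found in 9 of 19 lipogenic genes, whose median was 0.01, so it does not by itself mark carried-over tissue. Whether such tissue adds to the rise of the thermogenic list cannot be told from this share. The bound set for called members before the result was too weak, because Dio2 alone, near the floor, decides nothing.

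For the genes that fell, dilution of fat RNA by RNA of carried-over tissue was tested. The adipocyte markers had a median of -0.042 against -0.51 for the genes that fell, which were selected for being lower. The value near 0 argues against a dilution of adipocyte RNA large enough to give these falls. RNA of other resident cells was not tested this way, and all 12 endothelial markers were lower (median -0.13). A response to cold stays open and was not tested apart from the comparison of groups.

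For transcript usage, a candidate explanation of part of the calls is that transcripts stood at 0 in some libraries whatever their group: a median of 90 genes over the 9 other splits of the libraries (78 to 112) had a transcript at 0 in one whole group and above 0 in the other, against 153 in the real one. Other splits gave up to 83 calls. Whether such values of 0 come from Salmon's sharing of reads between overlapping transcripts or from the mice was not tested. A cold response in transcript choice stays open, and was not tested apart from the comparison of groups.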
